A study of Trypanosoma brucei brucei TREU927 with 4 samples.

How the data were processed

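RibOxi-seq libraries were made from small RNA of the post-ribosomal supernatant of procyclic *Trypanosoma brucei* TREU927. Per the labels' protocols, the ribosome-depleted supernatant was made in buffer with 300 mM KCl, 250 ng of RNA was fragmented with Benzonase for 30 min, and oxidation with beta-elimination and dephosphorylation preceded ligation. The submitters' processing notes name cutadapt 2.10, STAR 2.7.5c, SAMtools, UMI-tools 1.01 and bedtools 2.29.2, without their roles. The genome build and annotation are not given in the sources used here. UMI-tools handles molecular identifiers, but whether the counts are of distinct molecules is not stated.

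Both deposited tables were used. The count table deposited by the authors gives, per RNA and end position, the whole-number count of 3' ends in each library, not normalized. The candidate table deposited by the authors gives for 49 sites a count per library, a score per library that is a ratio of that count to a denominator, the mean ratio, the SD of the score and the mean count, the authors' signal level of the site. Dividing each count by its score gave a multiple of 0.5 in every case (to within 8.44e-09) and never less than 1, as a mean of 2 neighbouring counts with a floor of 1 would. The authors' construction of the score is not given in the sources used here, and neither is the reason why its counts differ from those of the count table. Positions in both tables coincide, since the correlation of their counts was 0.981 without an offset and at most 0.758 with an offset of 1 or 2 positions.

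RNAs were classed by their listed names. All names were also matched by locus tag or synonym to the RefSeq gene table of assembly ASM244v1, used for names, biotypes and lengths only. The match gave the tRNA class to names that do not state it. In all 41 names matched and all 41 were annotated as tRNA, among them sRNA-76 and some tRNAs already classed by name. For 39 of the 41 the last listed end equals the annotated length. No genome coordinates are given, since the build behind the tables is not named. Neither sequence nor genome was used here, so the planned comparison of candidate sites by base was not run. The RNAs 7SL and U5 are listed as 7SL_correct and U5_corrected, vault RNA as TBsRNA-10_VtRNA, telomerase RNA as TER and sRNA-76 as Tb927.4.4663_sRNA-76. The tRNAs named with an amino acid are listed with their chromosome, as in Tb927.11.tRNA_Glu_1 and Tb10_tRNA_Leu_1. The tables hold no reads, so reads shared by near-identical or overlapping RNAs show only where counts coincide, as for TBsRNA-40 and TBsRNA-45 with 13, 19, 18 and 20 counts each in replicates 2, 3, 4 and 5. Values on such RNAs are uncertain.

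Each position with a mean of at least 10 counts was compared with the rounded mean of up to 12 flanking positions, 6 on each side, in the same library, with unlisted positions taken as 0. The test was edgeR 4.0.16 quasi-likelihood (R 4.3.3) with library as a block, column totals as library sizes and Benjamini-Hochberg adjustment at 0.05. With no control and no other condition in the design, this compares a position with its neighbours and is not a test of methylation. Per-library enrichments are log2((count + 1)/(flank mean + 1)), averaged over libraries, and the pseudocount of 1 understates the enrichment where the flanks are low. Both values of a pair come from 1 library, so TMM or DESeq2 size factors are absorbed by the block and cannot change the result. On simulated data for this comparison, drawn for the 606 positions, 100 of 100 positions raised 2-fold and 100 of 100 raised 4-fold were recovered, and 1 of 406 unchanged positions (0.246%) was called. The simulated flanks were flat, drawn at the unraised mean of their position. These shares therefore do not tell how often the uneven flanks of the real data lead to a call.

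Candidate sites were compared with other positions by permuting labels within RNAs (100000 resamples, two-sided). The p-value is not given, because the listed sites all have a high score in the same libraries. With the labels kept and the enrichments shuffled within RNAs, this permutation test, run with fewer resamples, fell under 0.05 in 3 of 40 draws. With a log2 shift of 1 added at the listed positions it did so in 40 of 40. The shuffling is that of the test itself, so the first share does not check its assumptions on the real data. Classes were compared with Fisher's exact test over the tested positions. Agreement between libraries was measured on log2(CPM + 1), and replicate pairs were checked for excess similarity by chi-square tests over positions and over RNAs with at least 10 counts in a pair. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

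The tests, the classes and the rule for named sites were chosen before the data were examined. The rule took the 20 largest enrichments past the threshold with at least 50 counts and above the flanks in every library, every candidate site on snRNA, SL RNA, 7SL RNA, U3, vault RNA or telomerase RNA, the 10 candidate sites with the most counts, and up to 10 candidate sites not above the flanks in every library, of which there were none. RNAs were named when among the 10 with the most counts or the 5 with the most candidate sites. The sites that fell short of a score of 4 or a mean count of 10 were named after their values were seen. So were the 3 highest scores, and the score of 4 was taken from the lowest listed score. Alternatives covered the flank width and summary, the count minimum, DESeq2 1.42.0, limma 3.58.1, pseudocounts and each library left out in turn. A flank of 1 position on each side, the sum of replicates 2 and 4, the leave-one-out of the score counts, and a score without neighbours outside the listed range were added after the data were seen.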

Results

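Small RNA of procyclic *Trypanosoma brucei*, the insect-midgut form of the African sleeping sickness parasite, was examined with RibOxi-seq, which maps 2'-O-methylation of ribose from the 3' ends of RNA fragments. Oxidation removes fragment ends that carry a free 2' hydroxyl, so that ends at a 2'-O-methylated nucleotide are kept and ligated. The RNA came from the supernatant left after ribosomes were pelleted from cells grown at 27 °C in medium with 10% serum. The design held 1 group of 4 libraries, numbered replicates 2, 3, 4 and 5, with no unoxidised control and no other condition. Each question therefore concerned where along each RNA the 3' ends accumulated and how steadily they did so across libraries. The count table listed 10982 end positions on 303 RNAs, starting at position 20 of each RNA. Total counts were 32992 in replicate 2, 19885 in replicate 3, 26276 in replicate 4 and 23822 in replicate 5. At this depth 606 positions on 97 RNAs had a mean of at least 10 counts, and they held 53.2% of all counts. The labels do not state whether the replicates came from separate cultures, so the edgeR p-values measure only the spread between these samples, which may be technical. The Fisher and permutation p-values take positions as units and do not measure the spread between libraries, and positions on 1 RNA are not independent. The chi-square p-values measure departure from sampling noise.

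Transfer RNAs supplied about 1 of every 2 counted ends, 50.6% ± 3.23 (SD, n = 4) over 45 tRNAs. The C/D snoRNAs, most of which guide 2'-O-methylation, held 12.3% ± 1.78 over 86 RNAs, and the H/ACA RNAs, which guide pseudouridylation, held 8.15% ± 1.21 over 91 RNAs. The signal recognition particle (SRP) RNAs, 7SL RNA and the tRNA-like sRNA-76, held 10.3% ± 0.768 and thus took a large share for only 2 RNAs. The 5 spliceosomal snRNAs held 5.11% ± 0.361, and the spliced leader (SL) RNA, the donor of the 5' sequence joined to every trypanosome mRNA, held 1.97% ± 0.710. The remaining 73 RNAs, among them vault RNA, telomerase RNA and unclassified small RNAs, held 11.6% ± 2.31 (SD, n = 4).

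**Figure D1:**
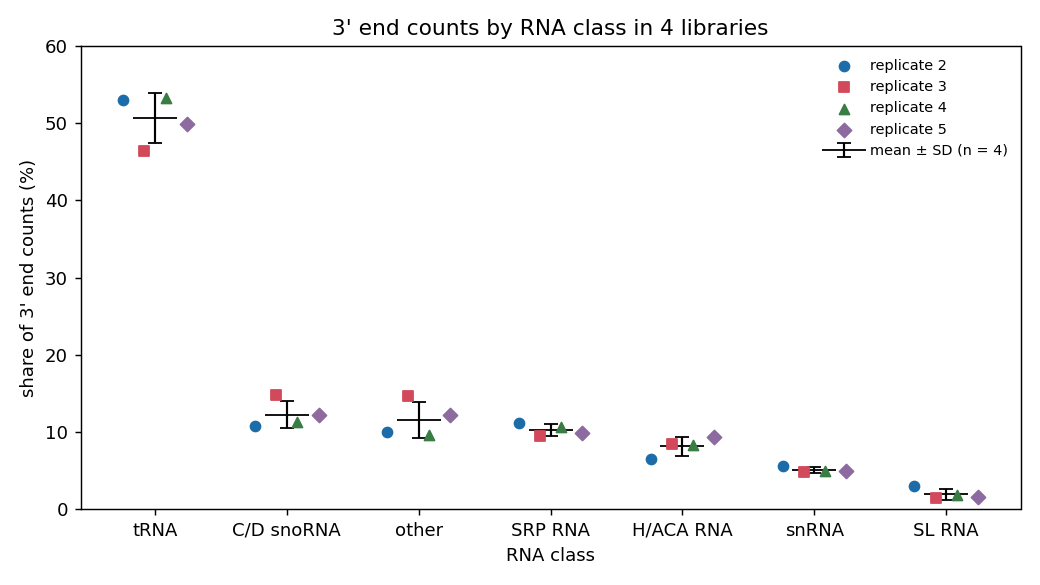
Share of 3' end counts (%) on the vertical axis for 7 RNA classes, with 1 marker per library and the mean ± SD of the 4 libraries in black. The tRNA share was 53.0% in replicate 2, 46.4% in replicate 3, 53.3% in replicate 4 and 49.9% in replicate 5, above every other class in each library.

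7SL RNA had the most counts of any RNA, a mean of 2077 ± 596 per library (SD, n = 4), or 7.98% ± 0.568 of the total. The next were tRNA_Glu_1 of chromosome 11 with 4.14% ± 0.285 and the tRNAs Tb927.4.3292 with 3.91% ± 0.185 and Tb927.4.4666 with 3.69% ± 0.228. The tRNAs Tb927.7.1175, Tb927.8.2856, Tb927.8.6566 and Tb927.7.6823 each held between 2.46% and 2.64%. The snoRNA U3, which acts in pre-rRNA processing, held 2.43% ± 0.585 and sRNA-76 held 2.31% ± 0.259. SL RNA was the least even of the named RNAs, with 2.99% of the counts in replicate 2 against 1.45%, 1.89% and 1.54% in replicates 3, 4 and 5. U2 snRNA, a core part of the spliceosome, held 1.80% ± 0.174.

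Over the tested positions, replicates 2 and 4 resembled each other most, and replicate 3 correlated least with the others. Across the 606 positions, Pearson's r of log2(CPM + 1) was 0.842 (Spearman's rho 0.799) between replicates 2 and 4, 0.757 (0.697) between 4 and 5, and 0.697 (0.626) between 2 and 5. Replicate 3 gave r = 0.506 (rho 0.502) with replicate 2, 0.521 (0.522) with replicate 4 and 0.624 (0.659) with replicate 5. These coefficients are across positions, which are not independent replicates. Over the 6 pairs the mean r was 0.658 ± 0.133 (SD). With every library thinned to the total of replicate 3, mean r was 0.715 among replicates 2, 4 and 5 and 0.534 with replicate 3. With the mean of each RNA removed the values were 0.778 and 0.668, a difference of 0.110 against 0.215 on all counts. Replicates 2 and 4 agreed within sampling noise over the 606 positions (chi-square per degree of freedom 1.02, p = 0.344), whereas the other 5 pairs did not. Summed per RNA they differed, with a chi-square per degree of freedom of 2.52 over 262 RNAs (p = 2.65e-36). By that measure replicates 4 and 5 were the closest pair, with 2.13 over 260 RNAs. Replicates 2 and 4 were kept as 2 samples, as labelled, although libraries made from 1 sample can differ in this way too. Summed as 1 sample, they gave 340 higher and 36 lower positions in the test of ends against flanks, in place of 343 and 38. SL RNA was among the RNAs that separated them, with 2.99% of the counts in replicate 2 and 1.89% in replicate 4.

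Ends piled up at single positions on every class of RNA. Of the 606 positions tested, 343 had more 3' ends than the mean of up to 12 flanking positions on the same RNA, 38 had fewer and 225 did not pass the test (edgeR quasi-likelihood test with library as a block, Benjamini-Hochberg adjusted p under 0.05). All 24 tested positions on H/ACA RNAs and all 31 on RNAs outside the named classes were higher than their flanks, as were 39 of 41 on C/D snoRNAs, 28 of 30 on spliceosomal snRNAs and 12 of 15 on SL RNA. On the densely covered tRNAs 173 of 372 tested positions were higher and 34 lower, and on the SRP RNAs 36 of 93 were higher and 4 lower. A position had to reach a mean of 10 counts to enter the test, which favours positions above their flanks. Set against the highest of the flanking counts in place of their mean, 113 positions were higher and 346 lower.

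The strongest enrichments among positions with at least 50 counts lay on an H/ACA RNA, an unclassified small RNA and telomerase RNA. By the log2 ratio of (count + 1) to (flank mean + 1), position 34 of the H/ACA RNA TB9Cs6H2 reached 6.04 ± 0.09 (SD, n = 4; 66.3 ± 4.03 counts), position 39 of TBsRNA-22 reached 5.74 ± 0.24 (65.8 ± 3.86 counts) and position 289 of telomerase RNA reached 4.88 ± 0.20 (65.5 ± 4.20 counts). The counts at these 3 ends were nearly equal library by library, so they cannot be taken as 3 separate ends. Telomerase RNA, the template RNA of telomere synthesis, had a further peak at position 981, just before its last listed end at 982, with 4.43 ± 0.73. Among tRNAs, Tb927.8.2857 had 4.51 ± 0.20 at position 35 and 2.30 ± 0.09 at position 25, and Tb927.5.445 had 3.67 ± 0.37 at position 32, where the mean count of 151 was among the highest seen. TBsRNA-76 had 3.37 ± 0.17 at position 464, and 7SL RNA had 2.85 ± 0.38 at position 107. Whether the authors' own counts hold this 7SL peak is taken up with their scores below. Enriched tRNA ends were also seen at Tb927.8.6562 position 26, Tb927.8.6564 position 82, Tb927.7.6823 position 70 and tRNA_Glu_1 position 30, with values between 2.41 and 2.66. Position 82 is the last listed end of Tb927.8.6564 and position 72, with 2.42 ± 0.24, that of sRNA-76, and ends of intact RNAs were not told apart from fragment ends there. None of the positions in this paragraph was among the authors' candidate sites, and all passed the edgeR test, with adjusted p between 3.32e-08 and 2.08e-06, and exceeded their flanks in 4 of 4 libraries.

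The authors' candidate sites of 2'-O-methylation were 49 positions on 30 RNAs, which address the question of which small RNAs outside the ribosome carry the mark. All 48 sites that reached the count minimum were higher than their flanks, in 4 of 4 libraries each, with 48 past the threshold over all positions tested and 48 adjusted over the list alone (edgeR, Benjamini-Hochberg). Against the highest flanking count 37 of the 48 were higher. The authors chose these sites on the same libraries, so the count is not independent evidence of methylation. The sites comprised 25 on 20 tRNAs, 10 on the SRP RNAs, 5 on spliceosomal snRNAs, 4 on C/D snoRNAs, 3 on SL RNA, 1 on an H/ACA RNA and 1 on vault RNA. The remaining site, position 37 of the tRNA Tb927.4.1219, had a mean of 9.75 counts, under the minimum. With no count minimum 49 of 49 sites were higher.

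Among the spliceosomal snRNAs, only U2 and U5 carried candidate sites. U5, which aligns exons in the spliceosome, had its tallest peak at position 44, with 36.5 ± 15.6 counts and a log2 enrichment of 3.17 ± 0.20 (SD, n = 4; adjusted p = 7.61e-08 by edgeR), about 8.97-fold. Its other site, position 47, rose less, by 1.35 ± 0.39 over 15.8 ± 4.27 counts, and lay below the tallest of its flanking positions, position 44, with a log2 ratio of -1.19 when that count was the reference. On U2, position 140 had 2.94 ± 0.78 (28.8 ± 16.2 counts), position 93 had 2.53 ± 0.30 (30.0 ± 7.44 counts) and position 28 had 2.02 ± 0.52 (19.3 ± 7.37 counts). Position 140 ranged from 10 counts in replicate 3 to 47 in replicate 2.

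SL RNA had candidate sites at positions 39, 63 and 111. Position 63 was the tallest, with 49.5 ± 23.5 counts and a log2 enrichment of 3.01 ± 0.19 (adjusted p = 7.61e-08 by edgeR), about 8.04-fold. Position 39 had 32.0 ± 10.4 counts and 2.11 ± 0.16, but its margin over the tallest flanking count was 0.43 and did not pass the test (adjusted p = 0.0792). Position 111 had 27.5 ± 21.5 counts and 2.46 ± 0.50, from 57 counts in replicate 2 to 7 in replicate 3. The listed ends began at position 20, and it was not checked whether the numbering starts at the capped 5' nucleotide.

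**Figure D2:**
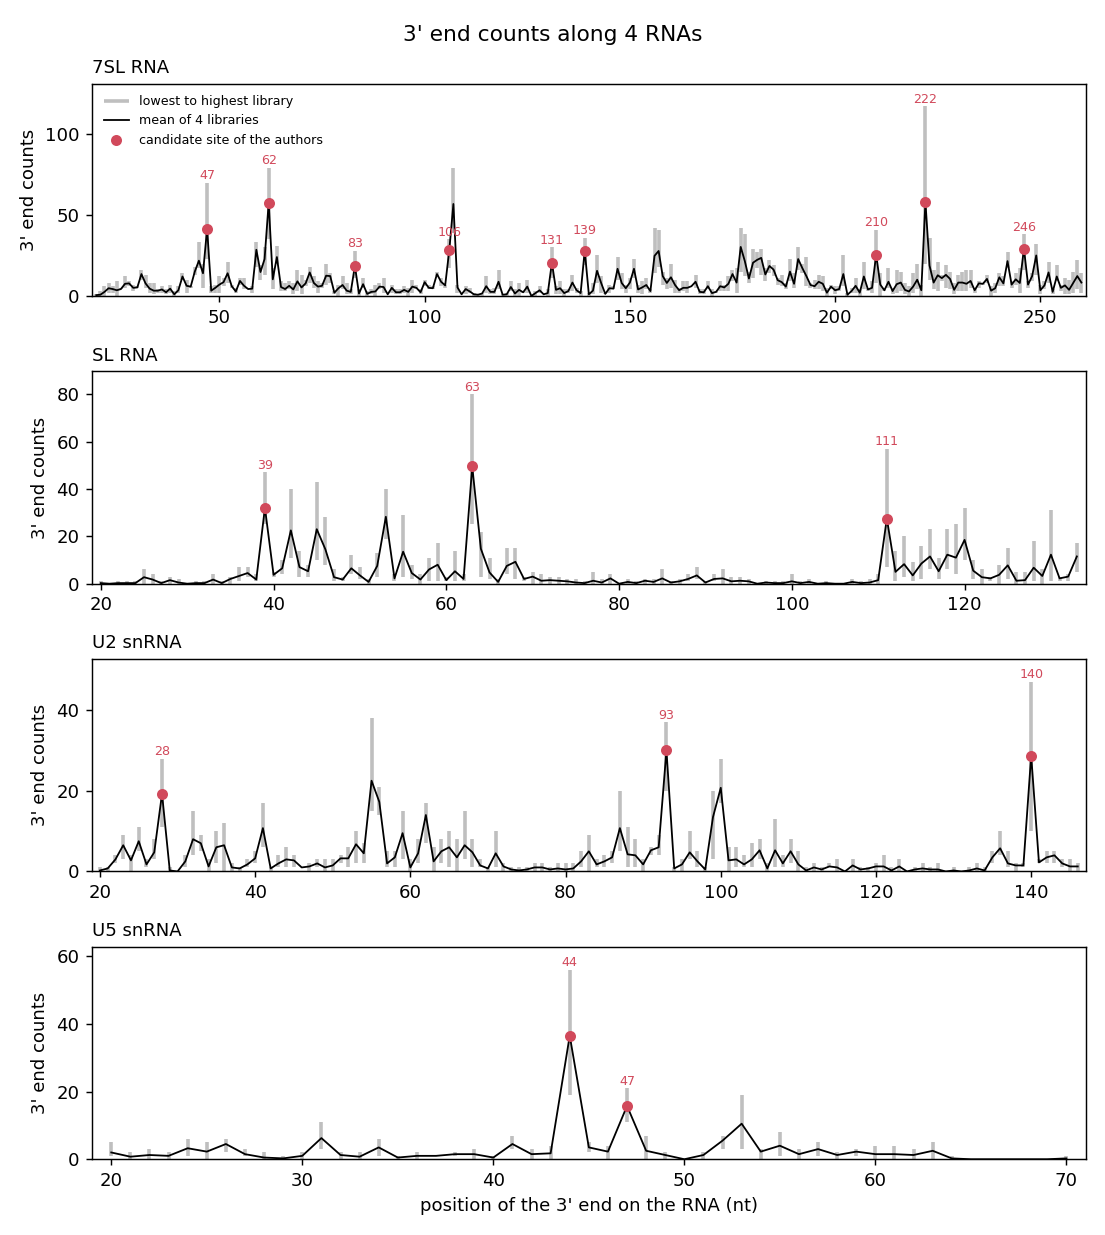
Counts of 3' ends (vertical axis, counts per library) by position in nucleotides (horizontal axis) along 7SL RNA, SL RNA, U2 and U5 snRNA, with the mean of 4 libraries in black, the lowest to highest library in grey and the authors' candidate sites in red. Position 44 of U5, positions 93 and 140 of U2 and position 63 of SL RNA stand above the positions directly beside them, some with lower peaks nearby. The 7SL peak at position 107, with a mean of 56.8 counts, is next to the candidate site at position 106, with 28.3.

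7SL RNA, the scaffold of the SRP that targets nascent proteins to the membrane, held 9 candidate sites, the most of any RNA. The tallest were position 222, with 58.3 ± 46.1 counts and a log2 enrichment of 2.30 ± 0.64, and position 62, with 57.5 ± 18.9 counts and 2.21 ± 0.37. Position 222 was uneven, with 117 and 73 counts in replicates 2 and 4 against 23 and 20 in replicates 3 and 5. Positions 139, 131, 210, 47 and 83 had 2.41 ± 0.32, 2.34 ± 0.27, 1.86 ± 0.34, 1.84 ± 0.47 and 1.79 ± 0.51. The lowest were position 106 with 1.40 ± 0.42 and position 246 with 1.28 ± 0.46. At position 106 the count table held 28.3 ± 7.80 counts beside 56.8 ± 16.8 at position 107, and with the 2 adjacent positions alone as flank the log2 ratio fell to -0.16 (adjusted p = 0.488 by edgeR). Position 246 exceeded its tallest flanking count by 0.16, which did not pass the test (adjusted p = 0.489).

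U3 snoRNA had candidate sites at position 48, with 22.8 ± 1.71 counts and a log2 enrichment of 2.14 ± 0.20, and at position 111, with 18.5 ± 9.26 counts and 1.86 ± 0.75. Position 48 exceeded its tallest flanking count by 0.44, which did not pass the test (adjusted p = 0.0722 by edgeR). Vault RNA, a small RNA of the vault ribonucleoprotein, had 1 site at position 70, with 18.0 ± 8.91 counts and 2.75 ± 0.37. The candidate table used here listed no site on telomerase RNA.

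**Figure D3:**
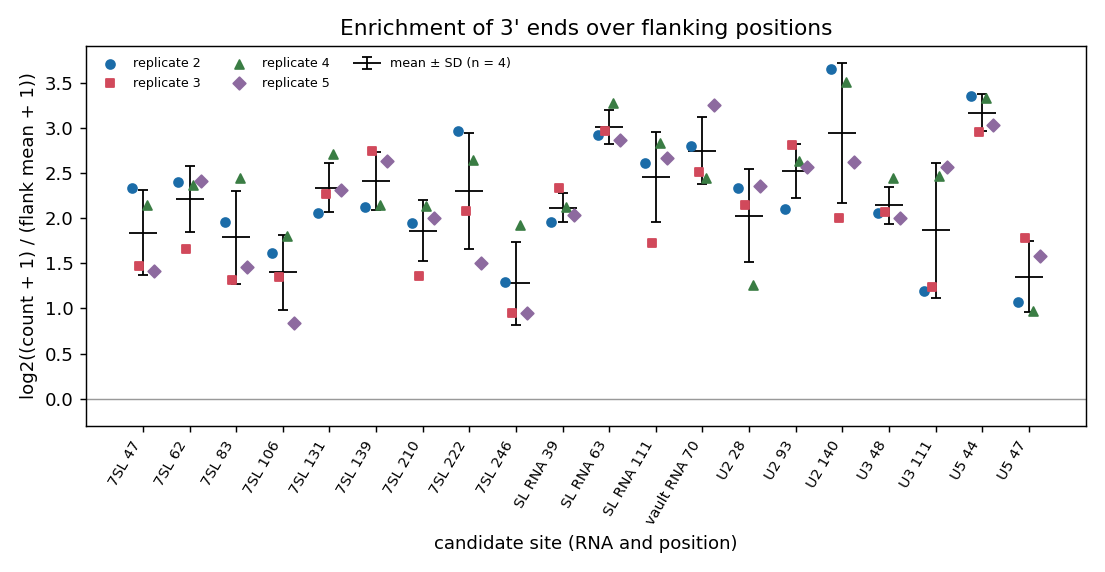
Log2 ratio of (count + 1) to (flank mean + 1) on the vertical axis for the 20 candidate sites on 7SL, SL, vault, U2, U3 and U5 RNA, with 1 marker per library and the mean ± SD (n = 4) in black. Every library lies above 0 at each of the 20 sites, and U5 position 44 has the highest mean, 3.17.

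Transfer RNAs carried the candidate sites with the most counts. The tRNA Tb927.4.4666 had 3 sites, with 130 ± 42.9 counts at position 44, 124 ± 25.2 at position 54 and 61.5 ± 8.23 at position 26, and log2 enrichments of 2.25 ± 0.45, 2.36 ± 0.26 and 2.85 ± 0.15 (SD, n = 4). tRNA_Glu_1 had 129 ± 63.0 counts at position 66 (1.99 ± 0.69), with 183 counts in replicate 2 and 43 in replicate 3, and its margin over the tallest flanking count, 0.43, did not pass the test (adjusted p = 0.159 by edgeR). Tb927.4.3292 had 98.0 ± 37.2 counts at position 43 (1.82 ± 0.62). Position 63 of the chromosome 10 tRNA_Leu_1 had 2.77 ± 0.36, position 66 of Tb927.7.7175 had 2.77 ± 0.14, position 57 of Tb927.3.4396 had 2.47 ± 0.31 and position 53 of Tb927.7.6823 had 2.45 ± 0.30. Over the 24 tested tRNA sites the median enrichment was 2.41, with a range from 1.53 to 3.87. Positions are counted along each RNA as listed. On chromosome 11 the last listed end was 109 for tRNA_Glu_1, 158 for tRNA_Phe_1, 100 for tRNA_Arg_1 and 84 for tRNA_His_1, none of which had an annotated length to compare, so the numbers need not be tRNA numbering.

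The candidate sites had a median log2 enrichment of 2.32 (quartiles 1.89 and 2.66) against 0.61 for the 558 other positions with at least 10 counts, a difference of 1.71. Every listed site has a high score in these same libraries, a ratio of its count to a denominator that may be local. This difference is therefore not independent of how the sites were listed, and no p-value is given for it. Labels permuted within RNAs gave a mean difference of 0.41. Other positions were also often enriched, with 295 of 558 higher than their flanks by edgeR. Among the 44 positions with a mean of at least 50 counts, which included 12 candidate sites, the difference was 0.22.

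Among positions with at least 10 counts, no RNA class passed the test for holding more or fewer candidate sites than the other classes. Candidate sites made up 20.0% of the tested positions on SL RNA, 16.7% on spliceosomal snRNAs, 10.8% on SRP RNAs, 9.76% on C/D snoRNAs, 6.45% on tRNAs, 4.17% on H/ACA RNAs and 3.23% on the remaining RNAs. The odds ratios ran from 3.03 for SL RNA and 2.48 for snRNAs to 0.603 for tRNAs and 0.374 for the remaining RNAs (Fisher's exact test, two-sided, adjusted p between 0.283 and 0.712 over 7 classes). Over all 10982 listed positions, with no count minimum, all 7 classes passed the test. The lowest mean count in the authors' candidate table was 10.0, so thinly covered positions could hardly have been listed. These odds ratios therefore reflect how densely each class was covered and are not a result about the classes. Positions on 1 RNA were also taken as independent, and the SL class is 1 RNA. The odds ratios were then 9.72 for SRP RNAs, 6.79 for SL RNA, 3.44 for snRNAs, 0.0866 for H/ACA RNAs and 0.0526 for the remaining RNAs, and those of tRNAs, 4.17, and C/D snoRNAs, 0.259, were opposite in direction to those at 10 or more counts (Fisher's exact test, largest adjusted p = 0.0204).

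The authors scored each site by a ratio of its count to a denominator whose construction is not given. In the authors' deposited table the mean score ran from 4.06 to 15.4 and the mean count from 10.0 to 138. The highest mean scores were 15.4 at 7SL position 139, 15.1 at position 65 of the chromosome 10 tRNA_Met_1 and 14.7 at SL RNA position 39. The counts in that table differed from the count table, with 23 of 196 equal, 108 lower and 65 higher, and the ratio of site means had a median of 0.959 (0.672 to 1.23). Scored on the count table against the mean of the 2 adjacent positions (at least 1), 44 of the 49 sites had a mean score of at least 4 and a mean count of at least 10. The 5 that did not were 7SL positions 62 and 106, position 62 of the chromosome 11 tRNA_Arg_1, position 43 of Tb927.4.3292 and position 37 of Tb927.4.1219. 7SL position 106 had a mean score of 8.40 in the authors' deposited table and 0.926 on the count table. The authors' count over their score there averaged 2.75, while the 2 adjacent positions averaged 31.6 in the count table. If the authors' denominator is the mean of the 2 adjacent counts, their counts lack a 7SL peak at position 107 of the height seen here. Since the construction of the score is not given, this stays conditional.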

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

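Each of the 63 groups of 4 library values was examined for a value far from the other 3 by Dixon's criterion (critical value 0.829), and 4 were found where chance alone gives about 3.15. Spliceosomal snRNAs held 5.65% of the counts in replicate 2 against a mean of 4.93% in the other libraries. The log2 enrichment at 7SL position 62 was 1.66 in replicate 3 against a mean of 2.39 elsewhere. U3 position 48 stood at 2.44 in replicate 4 against 2.04, and position 72 of sRNA-76, its last listed end, at 2.78 in replicate 3 against 2.31. A number of this size is what chance gives, and no cause was tested.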

How the results depend on the processing

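The flank of 1 position, the sum of replicates 2 and 4, and the alternatives of the score counts were chosen after the data were seen. Of 713 alternatives over 43 named sites, 706 left direction and call as they were, those with TMM or DESeq2 size factors by construction. Set against the highest flanking count, 4 sites no longer passed (7SL 246, SL RNA 39, tRNA_Glu_1 66 and U3 48), U5 47 turned to -1.19 and 7SL 106 to -0.996, and 7SL 106 stood at -0.16 with 1 flanking position on each side. The numbers of higher and lower positions, 343 and 38, became 113 and 346 with the highest flanking count, 632 and 596 with no count minimum and 44 and 0 with a minimum of 50, where fewer positions were tested. Lower positions numbered 73 with 3 flanking positions on each side, 78 with 1, 16 with the flank median and 23 with DESeq2. The higher share of all calls, 90.0%, was 81.2% with 3 positions, 79.5% with 1, 96.4% with the median, 24.6% with the highest flanking count, 51.5% with no minimum and 100% with a minimum of 50. Without any 1 library higher positions ranged from 308 to 336 and lower ones from 28 to 35, and with replicates 2 and 4 summed they were 340 and 36. Exchanging position and flank within libraries allows 8 arrangements, too few for a share under 0.05, and 1 of 8, the real one, gave 381 calls while the highest other gave 0.

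Of 48 candidate sites tested, 48 were higher than their flanks, 37 with the highest flanking count and 46 with 1 position on each side. With no minimum 49 of 49 were higher. A minimum of 50 left 12 to test, of which 12 were higher, and their difference from other positions was 0.22. With no minimum the odds ratios passed the test in every class (Fisher's exact test), with 4.17 for tRNA, 9.72 for SRP RNA, 3.44 for snRNA, 6.79 for SL RNA, 0.259 for C/D snoRNA, 0.0866 for H/ACA RNA and 0.0526 for the rest, against a background that counts thinly covered positions. Mean r between libraries was 0.395 with no minimum and 0.450 with a minimum of 50, and the cause was not tested. Without any 1 library, 40 to 45 candidate sites and 89 to 97 other positions reached a mean score of 4 and the count minimum. Class shares moved by less than 1 SD under each alternative run. At 19885 to 32992 counts per library, single positions rest on few counts. Candidate sites by base were not run.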

Other observations

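The tests on near-equal ends, on positions outside the candidate table and on recurring tRNA positions were all chosen only after the results were seen.

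Transfer RNAs, snoRNAs and other small RNAs carried sharp 3' ends that the candidate table used here did not hold. On the count table, 131 positions reached a mean score of 4 and a mean count of 10, of which 44 were candidate sites and 87, listed under 66 RNAs, were not. The 87 lay on tRNAs (22), H/ACA RNAs (21), the remaining RNAs (18), C/D snoRNAs (17), spliceosomal snRNAs (5), SL RNA (2) and SRP RNAs (2). Of them 7 were at the last listed end of their RNA, 7 were 1 position before it and 1 was at position 20, against 0 of the 44, and a neighbour outside the listed range counts as 0 in the score. With such neighbours left out, 83 positions outside the candidate table and 44 candidate sites reached the same minimum score and count. They include near-equal counts, at TB9Cs6H2 position 34, TBsRNA-22 position 39 and telomerase RNA position 289 and also at position 68 of the H/ACA RNA TB10Cs4H3 (17, 23, 13 and 22) and position 72 of the tRNA Tb927.5.445 (16, 23, 13 and 22), so 87 is an upper bound on separate ends. Examples, named after their values were seen, were SL RNA position 53 with a mean of 28.3 counts, vault RNA position 110 with 31.3, U2 position 100 with 20.8 and the C/D snoRNA TB9Cs2C1 position 69 with 36.8.

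The positions outside the candidate table may be ends that sit on thinly covered RNA, since their median flank count was 1.77 against 5.08 at the 44 candidate sites, a difference of -3.31 (permutation test, p = 4.00e-05). Replicate 3, the shallowest library, held a median of 32.1% of their summed CPM against 19.8% at candidate sites, a difference of 12.3 points (permutation p = 1e-05, the smallest possible), where equal raw counts in every library would give 31.3% and counts in proportion to depth 25%. Less the share of replicate 3 in the whole RNA class the difference was 7.65 points (permutation p = 6.00e-05), which argues against its different content of whole classes as the whole cause. Less the share in the other positions of the same RNA it was 4.47 points (permutation p = 0.0201). This second value cannot decide on whole RNAs, since some positions hold most counts of their RNA (96.4% at TB9Cs6H2 position 34) and leave few to correct with. Both corrections lowered the difference. Different content of whole RNAs therefore stays open, as does that of whole classes for part of the difference, and so do counts that did not scale with library totals. The authors' own counts, which differ from the count table at listed sites, are not given for these positions. Whether the positions reach a score of 4 on those counts is therefore not known. An unstated filter of the authors was not tested, nor was a biological explanation. The permutation p-values above take positions as units, but positions on the same RNA, or possibly counted from the same reads, are not independent. These p-values may therefore be too small, and they do not measure the spread between libraries. The shares of replicate 3 rest on that library alone.

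Position 34 of the H/ACA RNA TB9Cs6H2, position 39 of TBsRNA-22 and position 289 of telomerase RNA had almost the same counts, with 71 each in replicate 2, 62, 62 and 61 in replicate 3, 64 each in replicate 4 and 68, 66 and 66 in replicate 5. The largest summed difference between any 2 of them was 3, while 100000 draws of independent Poisson counts gave a median of 45, and 0 of them came as close, which argues against independent molecules. The same reads counted on 3 RNAs, through a shared sequence, is a candidate explanation. A ceiling on distinct molecules that is equal at every end is argued against by 6 other ends with higher means. Each exceeded the mean of the 3 ends, 65.8, by more than 3 Poisson SD, up to 151 at position 32 of Tb927.5.445. A ceiling that differs between ends was not tested. No biological explanation was tested.

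Candidate sites on different tRNAs may recur at shared position numbers. Positions 23, 26 and 53 each held sites on 3 tRNAs, and positions 25, 54, 62, 65 and 66 on 2 each, giving 14 pairs of sites at the same position number over 24 sites on 19 tRNAs. Sites redrawn among the tested positions of each tRNA gave a median of 6 pairs (permutation test, one-sided, p = 0.0134), but on the 15 tRNAs listed over exactly their annotated length there were 9 pairs against a median of 4, which did not pass (permutation p = 0.0634). Reads counted on both tRNAs of a pair would give near-equal counts, but 10 of the 14 pairs differed by more than in 95% of draws from 1 shared mean and 0 came unusually close. Part of the 14 pairs rests on chromosome 11 tRNAs listed up to position 158, and numbers were not aligned by sequence, so whether shared numbers mean shared places in the tRNA fold stays open.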
